A study of Homo sapiens with 18 samples.

How the data were processed

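The deposited values are intensity per the labels, made with MAS5 per the submitters' processing notes on a 3' expression array with 54675 probe sets, and were used on their linear scale. Total RNA had been extracted with TRIzol and a column kit with DNase, and 0.1 µg had been amplified to biotin-labelled cRNA from the 3' end. All 18 arrays were used, and columns were assigned to groups by their labels (0 columns could not be assigned). The sources used here name no genome build for the probe sets, so no coordinates are given, and the reference annotation (GRCh38.p14) served only to update gene names.

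The groups, comparisons, gene lists, named-gene rules and most checks were chosen before the data were examined. The written design took the values as already scaled between arrays. The files showed otherwise: the trimmed mean signal (2% trimmed) ran from 90.6 to 159 intensity units, a 1.75-fold range, with group means of 132, 141 and 136 in RWPE-1 and 96.0, 103 and 105 in LNCaP. Before any test was run, quantile normalization over all 18 arrays, until then meant as a check, was therefore made the primary analysis, and the values as deposited became a check. Equal distributions are assumed by this step, and the lines may differ in total messenger RNA, which these data cannot show.

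An offset of 2.49, the 20% quantile of all values, was added before taking log2. Of the probe sets, 62 controls were left out, and a probe set was kept if its signal exceeded the median of its array on at least 3 arrays, which 33788 did. Of the 54613 probe sets other than controls, 41091 carried 1 gene symbol, 1801 several and 11721 none, and 27476 of those kept carried 1 symbol. Each gene was represented by its probe set with the highest mean, and probe sets marked as prone to cross-hybridisation were used only where no other of the gene had been kept. This gave 14258 genes.

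Differences were tested with limma 3.58.1 in R 4.3.3, with 6 group means, moderated variances with an intensity trend (prior degrees of freedom 6.92, residual 12) and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05. Standard errors are those of the fit. Of 37 gene lists with 872 genes written from general knowledge, 726 genes were measured, and 36 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Because a preset correlation can be too low, camera was also run with an estimated correlation, and the rotation test fry was run as well. List members were in addition adjusted over the list alone.

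Genes named in the text came from fixed rules: the 10 largest rises and 10 largest falls of each 3D against 2D comparison and the 5 largest of each other comparison, up to 4 members of each called list, and 20 genes fixed in advance, of which 14 were tested and the rest are not analysed here. The largest rises and falls were taken among called genes whose mean in a compared group lay above the median of all gene means. Except for the differences between responses, the arrays of the groups also had not to overlap. By chance 3 against 3 arrays do not overlap in 10% of unchanged genes. For 3D against 2D the share of all genes without overlap was 41.4% and 55.5% in RWPE-1 at days 2 and 6, and 42.6% and 39.5% in LNCaP. Between the days it was 54.5% in RWPE-1 and 30.4% in LNCaP, and between the lines 72.6%.

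Chosen in advance as checks were the values as deposited, quantile normalization within each line, median centring, an offset of 1 and a larger offset of 14.6 (the median of all values), no filter, a stricter filter at the 75% quantile (17131 probe sets), the mean of all probe sets of a gene, no variance trend, array weights, only the arrays of the compared groups, replicate number as a block, and leaving out each array in turn. Trimmed mean scaling was added after the arrays were seen to be unscaled. Leaving out the arrays numbered 1 was added after an added control transcript, the dap spike, had been examined. Relative to the trimmed mean, its signal was lowest on these arrays in every group.

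The model fit was tested on simulated data with 14258 genes, of which 200 were changed. For RWPE-1 at day 6 against 2D it recovered 41.8%, 71.4% and 84.3% of changes of 0.5, 1 and 2, with 5.04% of calls false. For LNCaP the shares were 41.0%, 64.4% and 89.4% (4.38% false), and for the day 6 difference between the lines 17.9%, 55.4% and 80.9% (5.50% false). The simulated values had independent normal noise and entered the fit directly. Normalization, the filter and the choice of probe sets were therefore not tested. Far more than 200 genes were called in each real comparison, so these shares describe only a setting with few changes. The number of arrays limits the precision, and an exact permutation of 3 against 3 arrays cannot reach a p below 0.1.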

Results

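Messenger RNA was measured on 18 one-colour arrays covering 2 human prostate cell lines, with 3 arrays in each of 6 groups. RWPE-1 is an immortalized line of prostate epithelium kept in a serum-free keratinocyte medium, and LNCaP is a prostate cancer line kept in a medium with 10% fetal bovine serum, so line and medium always changed together. Each line was sampled as a monolayer on plastic coated with reconstituted basement membrane (2D), and inside gels of the same material (3D) at day 2, as clusters, and at day 6, as acini or spheroids. The comparisons address which transcripts differ between gel and monolayer in each line, how this shifts between the days, and whether the lines respond alike. The labels give no day for the 2D cultures, and the same 2D arrays of a line served both days. Differences between 3D and 2D therefore cannot be separated from time in culture. After a filter on dim probe sets, 14258 genes were tested, and 36 gene lists fixed beforehand could be tested as groups. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which can be technical. Changes are given on the log2 scale with the standard error of the fit, for 3 arrays against 3, and gene list values are medians over the members.

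Replicate arrays correlated at 0.979 to 0.985 across genes, arrays of different groups within a line at 0.951 to 0.978, and arrays of different lines at 0.741 to 0.764. The first principal component, which carried 79.8% of the variance, separated the lines. No array duplicated another. The lines also differed in signs of RNA labelling: the ratio of the 3' to the 5' control probe set for ACTB was 7.34 ± 1.24 in RWPE-1 and 3.33 ± 0.31 in LNCaP (SD, n = 9 each). The same ratio for the dap spike, a bacterial transcript added as a control, was 11.5 ± 1.48 in RWPE-1 and 2.87 ± 0.27 in LNCaP (SD, n = 9 each). The ratio was also higher in RWPE-1 for the thr spike (12.7 ± 7.97 and 3.75 ± 0.52) and the phe spike (2.21 ± 0.54 and 0.995 ± 0.13). It differed less between the lines for GAPDH (1.21 ± 0.05 and 1.12 ± 0.09) and for the lys spike (3.00 ± 0.44 and 2.75 ± 0.37). Within LNCaP the GAPDH ratio was 1.23 ± 0.02 in 2D, 1.04 ± 0.02 at day 2 and 1.08 ± 0.01 at day 6 without overlap between 2D and gel arrays (SD, n = 3 each). Within RWPE-1 the ACTB ratio was 6.56 ± 0.28 in 2D, 8.76 ± 1.07 in the gel at day 2 and 6.71 ± 0.61 at day 6 (SD, n = 3 each). From 2D to day 6 in RWPE-1 the phe ratio went from 1.81 ± 0.08 to 2.64 ± 0.21 and the dap ratio from 10.996 ± 1.15 to 13.1 ± 0.50, both without overlap (SD, n = 3 each).

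**Figure D1:**
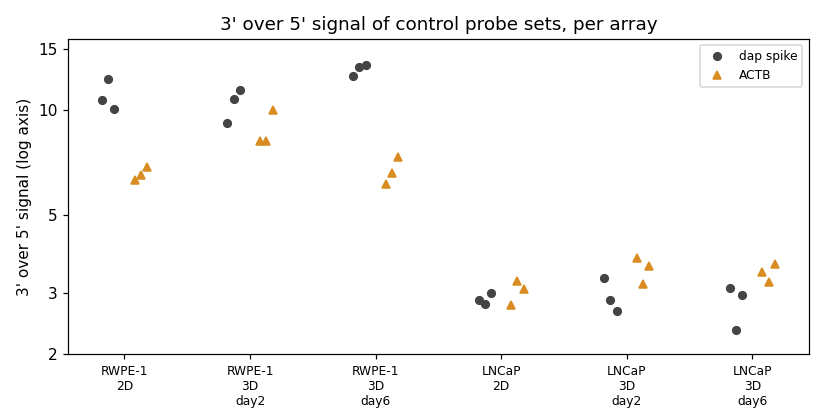
Ratio of 3' to 5' control probe set signal for ACTB and for the dap spike on each of the 18 arrays, by group. The RWPE-1 arrays lie above the LNCaP arrays for both transcripts, from 6.15 to 9.99 against 2.77 to 3.78 for ACTB.

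RWPE-1 cells that had spent 2 days in the gel lost interferon-stimulated and inflammatory transcripts and gained sterol and antioxidant transcripts. In the interferon response list, 19 of 28 genes fell and none rose (22 fell adjusted over the list alone), with a median of -0.77 and a camera adjusted p of 7.31e-14. Among its members OASL, an antiviral protein, changed by -2.06 ± 0.11 and the ubiquitin-like ISG15 by -1.52 ± 0.05. The NF-kB and inflammatory cytokine list had 10 of 20 genes lower and 0 higher (11 lower and 1 higher adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.62e-05). TNFAIP3, a feedback inhibitor of NF-kB, changed by -1.74 ± 0.14 and the NF-kB subunit RELB by -1.61 ± 0.19. Of 18 cholesterol synthesis genes 9 rose and 0 fell (13 rose adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.1e-07), including INSIG1, which retains the sterol sensor in the endoplasmic reticulum (1.74 ± 0.09), and the sterol oxidase MSMO1 (0.88 ± 0.07). Fatty acid synthesis genes rose in 8 of 13 cases and fell in 0 (also 8 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 8.55e-05), among them the lipogenic transcription factor SREBF1 (1.00 ± 0.11) and the desaturase SCD (0.67 ± 0.05). The NRF2 antioxidant list had 10 of 17 genes higher and 0 lower, the same numbers adjusted over the list alone (median 0.23, camera adjusted p = 1.13e-06), and the reductase AKR1C3 rose by 1.05 ± 0.11. AKR1C1 (2.52 ± 0.10) and AKR1C2 (2.50 ± 0.11) stood on probe sets that can cross-hybridise. With no filter, where another probe set represents each gene, their values were 0.79 and -0.28 and neither was called. Those probe sets had failed the filter on dim signals, so their values cannot decide which probe set is right. The other probe set of each that passed the filter gave 2.56 and 2.42, but it can cross-hybridise as well.

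Actin cytoskeleton and tight junction genes fell in part in the same comparison, while the desmosome and adherens junction list was not called (5 of 19 lower, 3 higher, also adjusted over the list alone) by camera (adjusted p = 0.243) but was called lower by fry (adjusted p = 0.00018). Of 23 actin cytoskeleton and SRF genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 1e-05), including the focal adhesion protein VCL (-0.78 ± 0.04). The tight junction and polarity list had 11 of 26 genes lower and 3 higher (12 and 3 adjusted over the list alone; median -0.21, camera adjusted p = 0.00315), led by CLDN1 (-2.46 ± 0.22) and OCLN (-1.65 ± 0.05), both strand-forming junction proteins. Among YAP/TAZ targets 7 of 23 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.30, camera adjusted p = 0.0059). The matricellular CCN1 changed by -1.04 ± 0.09. Immediate early genes fell in 9 of 21 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.34, camera adjusted p = 0.00776). The stress factor ATF3 changed by -1.02 ± 0.08. The integrin and hemidesmosome list (11 of 22 lower, 2 higher; 12 and 2 adjusted over the list alone; camera adjusted p = 0.00315) and the basement membrane and matrix list (6 of 21 lower, 2 higher; 7 and 2 adjusted over the list alone; camera adjusted p = 0.0157) lost their calls with an estimated correlation, at adjusted p = 0.162 and adjusted p = 0.0697. Within the latter the matrix glycoproteins TNC (-2.04 ± 0.17) and FN1 (-1.53 ± 0.12, or -0.96 with averaged probe sets) fell, while 1 of 6 other FN1 probe sets rose by 0.90. The unfolded protein response list (14 of 28 lower, 7 higher; 16 and 7 adjusted over the list alone; camera adjusted p = 0.0207) and the ribosome biogenesis list (7 of 25 lower, 0 higher, also adjusted over the list alone; camera adjusted p = 0.0395) were likewise not called with an estimated correlation, at adjusted p = 0.122 and adjusted p = 0.0736.

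The mitosis list as a whole lay slightly higher at this time, with 12 of 30 genes risen and 2 fallen (15 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 0.000443). Among the risen were the spindle proteins HMMR (0.83 ± 0.07) and ASPM (0.74 ± 0.07). Of 29 DNA replication genes 8 rose and 0 fell (9 adjusted over the list alone; median 0.15, camera adjusted p = 0.00315), a call that median centring ended (camera adjusted p = 0.0939). Among single genes, ID1, an inhibitor of basic helix-loop-helix factors, rose by 2.35 ± 0.07, the forkhead factor FOXQ1 by 2.14 ± 0.13 and the growth factor receptor FGFR3 by 1.76 ± 0.20. IGFBP3, which binds insulin-like growth factors, changed by -2.82 ± 0.05, the urokinase PLAU by -2.58 ± 0.32 and the actin nucleator COBL by -2.38 ± 0.13. The basal keratin KRT14 rose by 1.49 ± 0.28 and the laminin-binding integrin ITGA6 by 0.81 ± 0.12, while the intermediate filament gene VIM fell by 1.70 ± 0.11. The luminal keratins KRT8 (-2.27 ± 0.09) and KRT18 (-0.77 ± 0.04) also fell, both read from probe sets that can cross-hybridise. KRT5 (0.71 ± 0.37, limma adjusted p = 0.181), CDH1 (-0.15 ± 0.07, adjusted p = 0.112) and MKI67 (0.07 ± 0.10, adjusted p = 0.655) did not pass. In all, limma called 3382 genes, 1811 higher and 1571 lower, of which 222 and 248 changed by 1 or more. On the deposited scale, where the median of all genes lay 0.14 higher relative to that of the normalized values, 1957 genes were called, 1571 higher and 386 lower.

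By day 6 the RWPE-1 acini carried a hypoxia-type glycolytic programme, squamous differentiation transcripts and fewer cell cycle transcripts than the monolayers. In the hypoxia and glycolysis list 24 of 29 genes rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 1.03e-17). NDRG1, a stress-induced differentiation gene, rose by 3.82 ± 0.04, and BNIP3L, a mitophagy receptor, by 2.17 ± 0.04. The angiogenic factor VEGFA rose by 2.20 ± 0.05, or 1.60 when all its probe sets were averaged. Squamous differentiation genes rose in 21 of 33 cases and fell in 1, with the same numbers adjusted over the list alone (median 1.19, camera adjusted p = 1e-08). The cornified envelope precursor SPRR1B rose by 5.20 ± 0.31 and the protease inhibitor SERPINB3 by 4.63 ± 0.31. Its paralogue SPRR1A, which was near the floor in 2D, rose by 5.95 ± 0.52, or 3.77 with the larger offset and 4.97 with averaged probe sets. Desmosome and adherens junction genes rose in 13 of 19 cases and fell in 3, both also adjusted over the list alone (median 0.42, camera adjusted p = 0.000635), including the desmosomal cadherins DSC3 (1.30 ± 0.13) and DSC2 (1.19 ± 0.07, or 0.67 with averaged probe sets).

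Of 30 mitotic genes 26 fell and 0 rose at day 6 (27 and 1 adjusted over the list alone; median -0.68, camera adjusted p = 3.56e-12). The anaphase activator CDC20 changed by -1.24 ± 0.08 and the checkpoint kinase BUB1 by -1.20 ± 0.07. DNA replication genes fell in 18 of 29 cases and rose in 2, the same adjusted over the list alone (median -0.34, camera adjusted p = 0.00111). The helicase component CDC45 changed by -1.48 ± 0.13. Oxidative phosphorylation genes fell in 15 of 25 cases and rose in 0, also adjusted over the list alone (median -0.21, camera adjusted p = 0.00122), and averaging all probe sets of a gene ended that call (camera adjusted p = 0.0624). Immediate early genes were higher in 12 of 21 cases and lower in 3, with the same counts adjusted over the list alone (median 0.63, camera adjusted p = 0.000458), among them the activator protein subunit JUNB (1.51 ± 0.19) and the zinc finger factor EGR1 (1.35 ± 0.12). TGF-beta targets rose in 11 of 22 cases and fell in 6 (11 and 7 adjusted over the list alone; median 0.36, camera adjusted p = 0.0246). ID2 changed by 3.05 ± 0.08 and ID3 by 3.03 ± 0.13. That call was lost with the larger offset (camera adjusted p = 0.0516), with averaged probe sets (0.15) and when only the compared arrays were fitted (0.133). Basal markers (9 of 17 higher, 2 lower, also adjusted over the list alone; camera adjusted p = 0.0274) were not called with an estimated correlation (adjusted p = 0.0596) or after trimmed mean scaling (camera adjusted p = 0.14), though KRT16 (3.63 ± 0.29) and KRT15 (2.31 ± 0.36) rose. The unfolded protein response list (14 of 28 higher, 8 lower; the same adjusted over the list alone; camera adjusted p = 0.0155) and the lysosome and autophagy list (11 of 25 higher, 5 lower; the same adjusted over the list alone; camera adjusted p = 0.0274) gave adjusted p = 0.131 and adjusted p = 0.412 with an estimated correlation. Within them the pseudokinase TRIB3 rose by 1.70 ± 0.06 and the lysosomal transcription factor TFEB by 1.94 ± 0.10.

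Under the rules for named genes, the largest single rises at day 6 were in GJB6, a connexin of stratified epithelia (7.43 ± 0.23, or 6.75 with the larger offset), and LY6D, a surface antigen of squamous cells (7.52 ± 0.39, 6.58 with the larger offset and 6.81 without 2D replicate 3). Among the largest falls were the lipase inhibitor ANGPTL4 (-3.46 ± 0.33), the potassium channel KCNQ5 (-2.83 ± 0.21) and the protease inhibitor TFPI2 (-2.78 ± 0.18). The cyclin kinase inhibitor CDKN1A rose by 1.07 ± 0.08, MYC by 1.05 ± 0.06 and KRT14 by 1.70 ± 0.28, while VIM fell by 2.50 ± 0.11 and KRT8 by 2.39 ± 0.09. In all 6135 genes were called by limma, 2837 higher and 3298 lower, of which 732 and 520 changed by 1 or more. On the deposited scale, with the median of all genes 0.12 higher relative to the normalized values, the split was 2672 higher and 1819 lower.

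**Figure D2:**
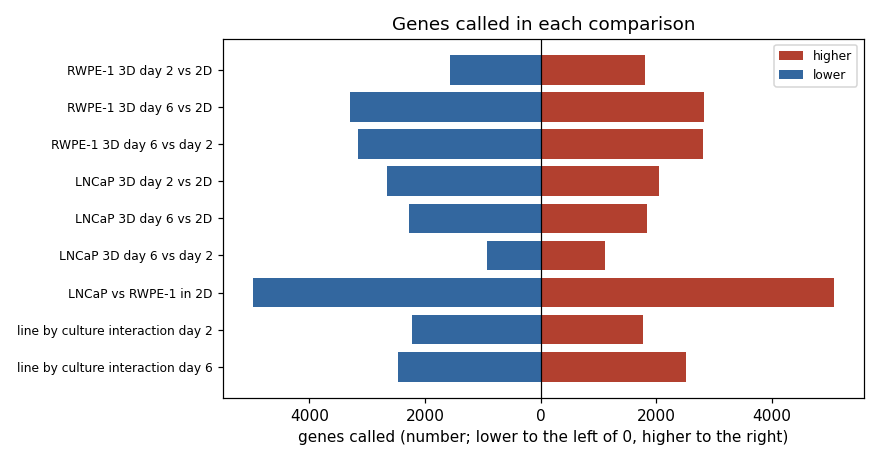
Number of genes called higher and lower by limma in each of the 9 comparisons, over 14258 genes tested. The line comparison in 2D had the most calls (10069) and LNCaP day 6 against day 2 the fewest (2043).

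Between day 2 and day 6 in RWPE-1 most cell cycle genes fell, and most hypoxia, squamous and interferon genes rose. Mitotic genes fell in 28 of 30 cases and rose in 0, also adjusted over the list alone (median -0.82, camera adjusted p = 9.88e-18). HMMR changed by -1.55 ± 0.07 and the kinase TTK by -1.50 ± 0.09. DNA replication genes fell in 23 of 29 cases and rose in 1, the same adjusted over the list alone (median -0.42, camera adjusted p = 2.77e-07). Hypoxia and glycolysis genes rose in 21 of 29 cases and fell in 2 (22 and 2 adjusted over the list alone; median 0.78, camera adjusted p = 1.02e-15). The vasodilator peptide ADM changed by 2.53 ± 0.10. Squamous genes rose in 23 of 33 cases and fell in 1, also adjusted over the list alone (median 1.75, camera adjusted p = 1.65e-10). The kallikrein protease KLK10 changed by 4.33 ± 0.19. Interferon response genes, which had fallen by day 2, rose in 23 of 28 cases and fell in 0, also adjusted over the list alone (median 0.76, camera adjusted p = 1.34e-09). The apoptosis-linked XAF1 changed by 2.74 ± 0.47. NF-kB and inflammatory cytokine genes rose in 10 of 20 cases and fell in 0, the same adjusted over the list alone (median 0.52, camera adjusted p = 0.00601). TNFAIP3 changed by 1.46 ± 0.14. The NRF2 antioxidant list turned down, with 9 of 17 genes lower and 2 higher (10 and 3 adjusted over the list alone; median -0.63, camera adjusted p = 0.000296), including the glutathione synthesis subunit GCLM (-1.42 ± 0.08) and the quinone reductase NQO1 (-1.38 ± 0.04).

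Immediate early genes rose in 15 of 21 cases between the days (also adjusted over the list alone; median 0.85, camera adjusted p = 2.53e-08), with KLF4, a factor of epithelial differentiation, at 1.75 ± 0.08. Unfolded protein response genes rose in 18 of 28 cases and fell in 3 (18 and 5 adjusted over the list alone; median 0.42, camera adjusted p = 7.48e-07). The chaperone DNAJB9 changed by 1.34 ± 0.07. Junction transcripts rose as well, in 14 of 19 desmosome and adherens junction genes (15 adjusted over the list alone; camera adjusted p = 7.48e-07) and in 12 of 26 tight junction and polarity genes (also 12 adjusted over the list alone; camera adjusted p = 0.000627). CLDN1 changed by 1.52 ± 0.22. Matrix protease and inhibitor genes rose in 14 of 29 cases and fell in 3 (16 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 0.00242). The metalloproteinase inhibitor TIMP3 changed by 3.78 ± 0.42. The other calls were oxidative phosphorylation (16 of 25 lower, 0 higher; 16 and 1 adjusted over the list alone; camera adjusted p = 7.6e-05), TGF-beta targets (10 of 22 higher, 3 lower, also adjusted over the list alone; camera adjusted p = 0.00582) and p53 targets (10 of 21 higher, 5 lower; 13 and 5 adjusted over the list alone; camera adjusted p = 0.0263, or 0.104 with averaged probe sets). Lysosome and autophagy genes (10 of 25 higher, 5 lower; 11 and 6 adjusted over the list alone) and basal markers (6 of 17 higher, 2 lower, also adjusted over the list alone) were called by camera (adjusted p = 0.0224 and adjusted p = 0.0404) but not with an estimated correlation (adjusted p = 0.323 and adjusted p = 0.06). CDKN1A rose by 1.32 ± 0.08 and MYC by 1.24 ± 0.06, while the receptor-responsive factor ETV5 fell by 1.87 ± 0.12. In total 5968 genes were called, 2813 higher and 3155 lower, of which 681 and 392 changed by 1 or more.

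**Figure D3:**
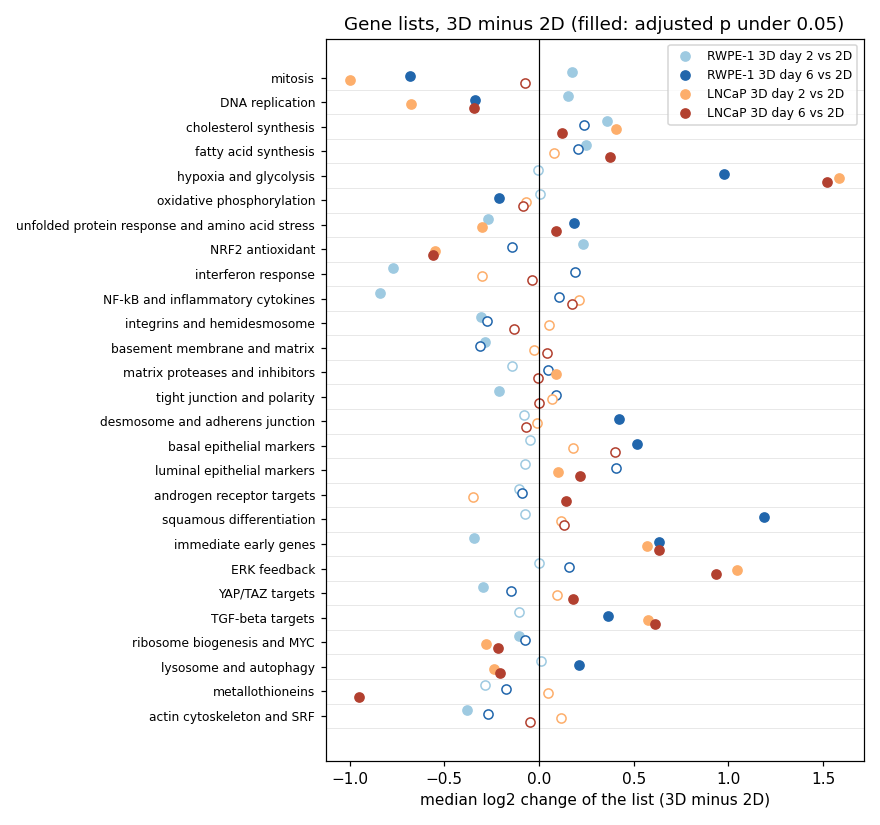
Median log2 change (3D minus 2D) of each gene list called in at least 1 comparison against 2D, for both lines and both days. Filled points have a camera adjusted p under the threshold, and the hypoxia and glycolysis list lies at 1.58 and 1.52 in LNCaP and at 0.98 in RWPE-1 at day 6.

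LNCaP cells responded to 2 days in the gel with a broad rise of hypoxia and glycolysis genes and a broad fall of cell cycle transcripts. In RWPE-1 at day 2, 7 of the 29 hypoxia and glycolysis genes had risen and 4 fallen (8 and 5 adjusted over the list alone), which camera did not call (adjusted p = 0.552) and fry called upward (adjusted p = 0.00165). The mean of the list on those arrays nevertheless lay slightly below 2D, between -0.09 and -0.03. In LNCaP 28 of these 29 genes rose and 0 fell, also adjusted over the list alone (median 1.58, camera adjusted p = 6.88e-42). The glycolytic enzyme ENO2 rose by 4.29 ± 0.18, NDRG1 by 3.38 ± 0.04 and the glycolysis regulator PFKFB3 by 3.33 ± 0.06. All 30 mitotic genes fell, also adjusted over the list alone (median -0.997, camera adjusted p = 2.53e-28). The spindle midzone protein PRC1 changed by -1.34 ± 0.09 and the survivin gene BIRC5 by -1.25 ± 0.08. DNA replication genes fell in 26 of 29 cases and rose in 1 (27 and 1 adjusted over the list alone; median -0.67, camera adjusted p = 7.69e-17). The ribonucleotide reductase subunit RRM2 changed by -1.22 ± 0.05. The ERK feedback list had 14 of 19 genes higher and 0 lower, also adjusted over the list alone (median 1.05, camera adjusted p = 5.1e-11), including the cyclin CCND1 (1.92 ± 0.04) and the ERK phosphatase DUSP6 (2.99 ± 0.07, or 3.60 with averaged probe sets). Immediate early genes rose in 14 of 21 cases and fell in 1 (15 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 8.97e-10). EGR1 changed by 5.23 ± 0.12. TGF-beta targets rose in 12 of 22 cases and fell in 1 (13 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 9.17e-08). ID1 changed by 4.23 ± 0.07 and ID3 by 3.30 ± 0.13.

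Cholesterol synthesis genes rose in 9 of 18 cases in LNCaP at day 2 and fell in 1, also adjusted over the list alone (median 0.40, camera adjusted p = 2.38e-05). The sterol carrier STARD4 changed by 2.23 ± 0.09 and the synthase HMGCS1 by 1.77 ± 0.06. Ribosome biogenesis genes fell in 18 of 25 cases and rose in 0 (19 adjusted over the list alone; median -0.28, camera adjusted p = 2.47e-05), including the assembly factor RRS1 (-0.83 ± 0.15). NRF2 antioxidant genes fell in 9 of 17 cases and rose in 2, the same adjusted over the list alone (median -0.55, camera adjusted p = 0.000148). NQO1 changed by -1.004 ± 0.04. The calls for the unfolded protein response list (16 of 28 lower, 5 higher; 17 and 5 adjusted over the list alone; camera adjusted p = 0.00243) and the lysosome and autophagy list (12 of 25 lower, 3 higher; 15 and 3 adjusted over the list alone; camera adjusted p = 0.00326) were lost with an estimated correlation, at adjusted p = 0.059 and adjusted p = 0.173. Luminal markers (6 of 18 higher, 2 lower, also adjusted over the list alone; camera adjusted p = 0.00686) and matrix proteases and inhibitors (8 of 29 higher, 3 lower; 9 and 3 adjusted over the list alone; camera adjusted p = 0.0326) gave adjusted p = 0.059 and adjusted p = 0.114 that way. The protease call was also lost with averaged probe sets (camera adjusted p = 0.0813) and without day 2 replicate 3 (0.0783). Members of these lists that rose were the secreted AGR2 (2.66 ± 0.26), KRT8 (1.69 ± 0.09), the matrix metalloproteinase MMP10 (4.43 ± 0.26) and its inhibitor TIMP1 (1.96 ± 0.08).

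Among the largest single rises in LNCaP at day 2, IGFBP3 changed by 5.63 ± 0.05 and the trefoil peptide TFF1 by 4.92 ± 0.24. The kinase scaffold AKAP12 rose by 6.90 ± 0.17, the retinoic acid hydroxylase CYP26A1 by 5.88 ± 0.32 and the collagen-modifying PLOD2 by 5.49 ± 0.23, and with the larger offset these were 5.88, 4.23 and 4.25 (5.79 for AKAP12 with averaged probe sets). The olfactory receptor OR51E1 fell by 3.03 ± 0.26, the transcription factor MAF by 2.14 ± 0.22 and the arginase ARG2 by 2.09 ± 0.08. TMEFF2, a membrane protein of prostate, fell by 3.74 ± 0.31 (-1.62 with averaged probe sets), while another of its probe sets rose by 1.71. CDKN1A rose by 1.24 ± 0.08 and the laminin subunit LAMB3 by 1.65 ± 0.21, while MKI67 fell by 0.99 ± 0.10. KLK3, which encodes prostate-specific antigen (-0.01 ± 0.13, limma adjusted p = 0.954), and CDH1 (0.01 ± 0.07, adjusted p = 0.912) did not pass. The fit called 4700 genes, 2045 higher and 2655 lower, of which 448 and 337 changed by 1 or more. With the values as deposited, whose median lay 0.10 higher relative to the normalized ones, 2328 genes were called, 1483 higher and 845 lower.

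At day 6 the hypoxia, ERK feedback and immediate early lists were higher in LNCaP spheroids than in 2D. Of 30 mitotic genes 10 were lower than in 2D and 3 higher, also adjusted over the list alone (median -0.0722), which camera did not call against other genes (adjusted p = 0.343) and fry called lower than 2D (adjusted p = 0.00167). Hypoxia and glycolysis genes rose in 28 of 29 cases and fell in 0, also adjusted over the list alone (median 1.52, camera adjusted p = 3.26e-51). ADM changed by 4.08 ± 0.10 and NDRG1 by 3.60 ± 0.04. ERK feedback genes rose in 12 of 19 cases and fell in 0 (13 adjusted over the list alone; median 0.93, camera adjusted p = 7.6e-13). The phosphatase DUSP4 changed by 2.14 ± 0.15 and CCND1 by 1.21 ± 0.04. Immediate early genes rose in 11 of 21 cases and fell in 2 (12 and 2 adjusted over the list alone; median 0.63, camera adjusted p = 6.3e-08). EGR1 changed by 3.94 ± 0.12. TGF-beta targets rose in 12 of 22 cases and fell in 0 (12 and 1 adjusted over the list alone; median 0.61, camera adjusted p = 6.73e-07). The circadian repressor BHLHE40 changed by 3.69 ± 0.09 and ID1 by 3.46 ± 0.07. Part of the lipid synthesis genes rose, with 6 of 13 fatty acid genes higher and 2 lower (8 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.000118). Among the risen were SCD (1.35 ± 0.05) and the synthase FASN (1.30 ± 0.09, or 0.79 with averaged probe sets). Cholesterol synthesis genes rose in 8 of 18 cases and fell in 1, also adjusted over the list alone (median 0.12, camera adjusted p = 0.00071). Androgen receptor targets rose in 11 of 30 cases and fell in 6 (12 and 6 adjusted over the list alone; median 0.14, camera adjusted p = 0.0151). The prostaglandin receptor PTGER4 changed by 1.52 ± 0.09. The unfolded protein response list had 13 of 28 genes higher and 4 lower (13 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.000607). The stress factor DDIT3 changed by 2.15 ± 0.11.

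Metallothioneins, which bind metal ions, fell in 6 of 9 cases at day 6 and rose in 1, also adjusted over the list alone (median -0.95, camera adjusted p = 1.15e-05), with MT2A at -0.998 ± 0.04 from a probe set that can cross-hybridise within the family. NRF2 antioxidant genes fell in 10 of 17 cases and rose in 1, the same adjusted over the list alone (median -0.56, camera adjusted p = 3.7e-07). NQO1 changed by -1.05 ± 0.04. DNA replication genes fell in 23 of 29 cases and rose in 0 (24 and 1 adjusted over the list alone; median -0.34, camera adjusted p = 1.41e-07), and ribosome biogenesis genes in 13 of 25 cases, also adjusted over the list alone (median -0.22, camera adjusted p = 0.000172). Lysosome and autophagy genes (13 of 25 lower, 1 higher; 14 and 1 adjusted over the list alone; camera adjusted p = 0.000444) and luminal markers (5 of 18 higher, 1 lower, also adjusted over the list alone; camera adjusted p = 0.0151) were not called with an estimated correlation, at adjusted p = 0.128 and adjusted p = 0.0692. YAP/TAZ targets (9 of 23 higher, 2 lower; 10 and 2 adjusted over the list alone; camera adjusted p = 0.0244) were not called without day 6 replicate 1 (camera adjusted p = 0.0546) or when only the compared arrays were fitted (0.0967). PLOD2 rose by 6.24 ± 0.23 and the membrane protein TMEM100 by 5.78 ± 0.26 (4.98 and 4.67 with the larger offset), and IGFBP3 by 4.97 ± 0.05. The Notch ligand JAG1 fell by 1.66 ± 0.08, the melanosomal glycoprotein GPNMB by 1.71 ± 0.13 and OR51E1 by 2.28 ± 0.26. MKI67 (-0.15 ± 0.10, limma adjusted p = 0.299) and KLK3 (0.27 ± 0.13, adjusted p = 0.13) did not pass. The fit called 4121 genes, 1846 higher and 2275 lower, of which 353 and 162 changed by 1 or more. As deposited, with the median 0.12 higher relative to the normalized values, 1708 were called, 1322 higher and 386 lower.

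**Figure D4:**
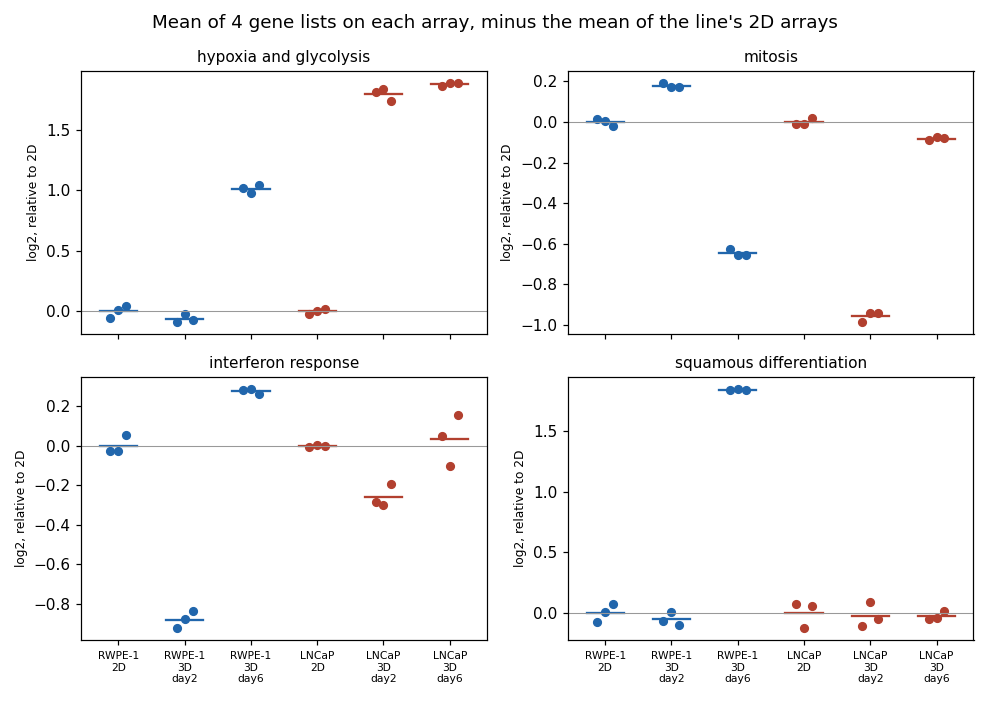
Mean log2 level of gene lists on each array relative to the 2D mean of its line, by group. In LNCaP the mitosis list lay between -0.99 and -0.94 on the day 2 arrays and between -0.09 and -0.08 on the day 6 arrays.

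From day 2 to day 6 in the gel, all 30 mitotic genes rose in LNCaP, also adjusted over the list alone (median 0.86, camera adjusted p = 4.74e-51), the opposite of RWPE-1 over the same days. ASPM changed by 1.43 ± 0.07 and the centromere protein CENPF by 1.23 ± 0.09. DNA replication genes rose in 19 of 29 cases and fell in 1 (22 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 5.96e-16). The thymidine kinase TK1 changed by 0.89 ± 0.07. Unfolded protein response genes rose in 19 of 28 cases and fell in 0 (23 adjusted over the list alone; median 0.44, camera adjusted p = 1.33e-23). DDIT3 changed by 2.07 ± 0.11 and TRIB3 by 1.503 ± 0.06. Androgen receptor targets rose in 16 of 30 cases and fell in 1 (19 and 2 adjusted over the list alone; median 0.49, camera adjusted p = 2.76e-11). The androgen-conjugating UGT2B17 changed by 1.499 ± 0.26 and the kallikrein KLK2 by 1.37 ± 0.29. At day 2 against 2D, 16 of the 30 androgen receptor targets had been lower and 6 higher (17 and 6 adjusted over the list alone; median -0.35), which camera did not call (adjusted p = 0.0599) but fry did (adjusted p = 0.0021), as did camera with no filter (adjusted p = 0.0231) and as deposited (adjusted p = 0.0167). Metallothioneins fell in 7 of 9 cases, also adjusted over the list alone (median -0.74, camera adjusted p = 2.07e-13). Fatty acid synthesis genes rose in 8 of 13 cases and fell in 1, the same adjusted over the list alone (median 0.28, camera adjusted p = 7.35e-05), and interferon response genes in 7 of 28 cases (9 adjusted over the list alone; median 0.23, camera adjusted p = 0.0028). The antiviral helicase DDX60 changed by 0.95 ± 0.13. At day 2 against 2D, 12 of the 28 interferon genes had been lower and 0 higher, also adjusted over the list alone (median -0.30), which camera narrowly did not call (adjusted p = 0.0529). It was called by fry (adjusted p = 9.4e-06) and by camera under many alternatives, among them no filter (adjusted p = 0.0188), averaged probe sets (adjusted p = 0.019), median centring (adjusted p = 0.0327) and the replicate block (adjusted p = 0.034). Cholesterol synthesis genes fell in 5 of 18 cases and rose in 0 (5 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.00462). HMGCS1 changed by -0.92 ± 0.06. Heat shock genes fell in 5 of 15 cases and rose in 0 (6 adjusted over the list alone; median -0.20, camera adjusted p = 0.00503), with the chaperone HSPH1 at -0.32 ± 0.05, a gene that was not called as deposited (-0.30).

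TGF-beta targets fell in 7 of 22 cases between the days in LNCaP and rose in 2, also adjusted over the list alone (median -0.13, camera adjusted p = 0.0245, or 0.0715 without day 6 replicate 3 and 0.0505 with the stricter filter). ID3 changed by -1.18 ± 0.13. Matrix proteases and inhibitors (7 of 29 lower, 1 higher, also adjusted over the list alone; camera adjusted p = 0.0126), actin genes (7 of 23 lower, 0 higher, also adjusted over the list alone; camera adjusted p = 0.0128), immediate early genes (6 of 21 lower, 2 higher; 7 and 2 adjusted over the list alone; camera adjusted p = 0.0284) and integrins (6 of 22 lower, 2 higher; 8 and 2 adjusted over the list alone; camera adjusted p = 0.0355) lost their calls with an estimated correlation. Those values were adjusted p = 0.0635, adjusted p = 0.0825, adjusted p = 0.0514 and adjusted p = 0.317. Without single arrays the last 3 were also lost: the actin call without day 2 replicate 2 (camera adjusted p = 0.0678), the immediate early call without day 6 replicate 3 (0.0715) and the integrin call without day 2 replicate 2 (0.0946) or day 6 replicate 1 (0.211). The protease inhibitor SLPI rose by 1.90 ± 0.08, while the lectin REG4 fell by 3.47 ± 0.42, TFF1 by 2.54 ± 0.24 and the xenobiotic oxidase CYP1A1 by 1.69 ± 0.11. MKI67 rose by 0.84 ± 0.10 (0.55 with averaged probe sets) and CCND1 fell by 0.71 ± 0.04. The fit called 2043 genes, 1117 higher and 926 lower, of which 125 and 86 changed by 1 or more, against 569 with the values as deposited, 396 higher and 173 lower.

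On coated plastic basal transcripts and most squamous transcripts were lower in LNCaP than in RWPE-1, and most androgen receptor targets were higher. All 17 basal markers were lower in LNCaP, also adjusted over the list alone (median -6.47, camera adjusted p = 5.16e-09), with the caveolae protein CAV1 at -10.58 ± 0.36 and the keratins KRT14 at -8.70 ± 0.28 and KRT5 at -8.27 ± 0.37. With the larger offset these were -8.85, -7.08 and -6.80, since LNCaP lay near the floor for them. Androgen receptor targets were higher in 20 of 30 cases and lower in 7, also adjusted over the list alone (median 1.68, camera adjusted p = 0.000524), with KLK3 at 11.01 ± 0.13, the serine protease TMPRSS2 at 7.95 ± 0.15 and the metalloreductase STEAP2 at 7.58 ± 0.13. The larger offset gave 8.87, 6.28 and 6.87 for them, and averaging all probe sets gave 6.98 for KLK3 and 5.33 for TMPRSS2. ERK feedback genes were lower in 18 of 19 cases and YAP/TAZ targets in 21 of 23, with 1 higher in the latter (medians -2.94 and -2.89, camera adjusted p = 1.88e-08 and adjusted p = 5.6e-08), both also adjusted over the list alone, among them MYOF, a membrane repair protein (-6.52 ± 0.10, or -5.21 with averaged probe sets). Interferon response genes were lower in 22 of 28 cases and higher in 1 (median -2.18, camera adjusted p = 9.72e-07) and NF-kB genes lower in 18 of 20 (median -2.46, camera adjusted p = 2.91e-05), both also adjusted over the list alone. The cytokine IL1B differed by -6.65 ± 0.12. Mitotic genes were lower in 27 of 30 cases and higher in 2 (median -1.05, camera adjusted p = 1.15e-07) and DNA replication genes lower in 24 of 29 and higher in 2 (median -0.85, camera adjusted p = 6.89e-06), the same adjusted over the list alone. The mitotic kinase AURKA differed by -2.29 ± 0.05. Unfolded protein response genes were higher in 22 of 28 cases and lower in 4, also adjusted over the list alone (median 1.11, camera adjusted p = 9.52e-05), including the serine synthesis enzyme PHGDH (2.91 ± 0.09).

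Also lower in LNCaP in 2D, with equal counts adjusted over the list alone, were 9 of 9 metallothioneins (camera adjusted p = 1.4e-05), 19 of 25 ribosome biogenesis genes with 5 higher (0.000642), 15 of 21 immediate early genes with 2 higher (0.000849), 17 of 23 actin genes with 3 higher (0.000922), 21 of 33 squamous genes with 3 higher (0.0019) and 13 of 19 desmosome genes with 5 higher (0.0255). Integrins (18 of 22 lower, 1 higher; camera adjusted p = 4.51e-05), basement membrane genes (14 of 21 lower, 5 higher; camera adjusted p = 0.0155) and lysosome genes (16 of 25 higher, 4 lower; camera adjusted p = 0.0116) kept the same counts adjusted over the list alone. None of these 3 was called with an estimated correlation, at adjusted p = 0.0568, adjusted p = 0.0568 and adjusted p = 0.236. The lysosome call was also lost as deposited (camera adjusted p = 0.11) and after median centring (0.0566), and it and the basement membrane call were lost with quantile normalization within each line (0.0528 and 0.0821). VIM differed by -3.95 ± 0.11, ITGA6 by -3.30 ± 0.12 and the E-cadherin gene CDH1 by 0.99 ± 0.07 (0.53 with averaged probe sets and 0.44 as deposited). In total 10069 genes were called, 5085 higher and 4984 lower in LNCaP, of which 2864 and 2532 differed by 1 or more. As deposited the median of all genes shifted by -0.26 and the split was 3597 higher and 5968 lower, and with quantile normalization within each line it shifted by -0.29, with 3844 higher and 6480 lower. Trimmed mean scaling shifted the median by 0.16. Line, medium and the 3' to 5' ratios changed together here, so this comparison does not separate them.

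The lines were then compared in their response to the gel, as the change in LNCaP minus the change in RWPE-1. An upward difference can come from a rise in LNCaP or a fall in RWPE-1, and a downward one from the reverse. At day 2 hypoxia and glycolysis genes rose more in LNCaP in 27 of 29 cases and less in 1, also adjusted over the list alone (median difference 1.502, camera adjusted p = 6.2e-34). ADM differed by 3.72 ± 0.14. All 30 mitotic genes differed downward, also adjusted over the list alone (median -1.09, camera adjusted p = 2.31e-29), as did 25 of 29 DNA replication genes, the same adjusted over the list alone (median -0.85, camera adjusted p = 2.86e-18). HMMR differed by -1.70 ± 0.10 and RRM2 by -1.37 ± 0.07. Immediate early genes differed upward in 15 of 21 cases (17 adjusted over the list alone; median 1.13, camera adjusted p = 3.24e-12), ERK feedback genes in 12 of 19 with 2 downward (14 and 2 adjusted over the list alone; median 1.00, camera adjusted p = 3.82e-09) and TGF-beta targets in 14 of 22 with 2 downward (15 and 2 adjusted over the list alone; median 1.06, camera adjusted p = 3.25e-07), with EGR1 at 4.72 ± 0.17, CCND1 at 2.26 ± 0.05 and BHLHE40 at 2.43 ± 0.12. NRF2 antioxidant genes differed downward in 12 of 17 cases and upward in 1 (13 and 1 adjusted over the list alone; median -0.75, camera adjusted p = 1.64e-08). The glutathione synthesis enzyme GCLC differed by -1.69 ± 0.07. IGFBP3, which fell in RWPE-1 and rose in LNCaP, differed by 8.45 ± 0.07. KRT8 differed by 3.95 ± 0.13 and VIM by 2.01 ± 0.15. In all 3989 genes differed by limma, 1770 upward and 2219 downward, 618 and 558 of them by 1 or more. After median centring the split was 2192 upward and 1764 downward, and as deposited 1897 genes differed.

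Part of the NF-kB, interferon, actin and tight junction genes also differed upward at day 2. NF-kB genes did so in 11 of 20 cases (14 adjusted over the list alone; median 1.27, camera adjusted p = 9.7e-06), interferon genes in 10 of 28, also adjusted over the list alone (median 0.42, camera adjusted p = 3.07e-05), and actin genes in 10 of 23 with 1 downward, also adjusted over the list alone (median 0.67, camera adjusted p = 9.47e-06). The focal adhesion protein ZYX differed by 1.31 ± 0.17. The mean of the interferon list lay below 2D in both lines at day 2. On the gel arrays it was between -0.30 and -0.20 in LNCaP and between -0.93 and -0.84 in RWPE-1. Matrix proteases (13 of 29 upward, 2 downward, also adjusted over the list alone; camera adjusted p = 0.000222), tight junction genes (10 of 26 upward, 2 downward; 11 and 2 adjusted over the list alone; camera adjusted p = 0.00413), luminal markers (6 of 18 upward, 2 downward, also adjusted over the list alone; camera adjusted p = 0.00301) and YAP/TAZ targets (9 of 23 upward, 3 downward, also adjusted over the list alone; camera adjusted p = 0.0091) were called too. OCLN differed by 1.72 ± 0.07 and CCN1 by 2.20 ± 0.13. The integrin (9 of 22 upward, 5 downward; 10 and 5 adjusted over the list alone; camera adjusted p = 0.00388), lysosome (12 of 25 downward, 3 upward; camera adjusted p = 0.00688) and basement membrane lists (6 of 21 upward, 2 downward; camera adjusted p = 0.0248) were not called with an estimated correlation, at adjusted p = 0.162, adjusted p = 0.209 and adjusted p = 0.0749. The same held for p53 targets (6 of 21 upward, 3 downward; 8 and 3 adjusted over the list alone; camera adjusted p = 0.0437) and mesenchymal genes (6 of 18 upward, 2 downward; camera adjusted p = 0.0438), at adjusted p = 0.0656 and adjusted p = 0.0749. Lists given without a second count kept the same numbers adjusted over the list alone.

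At day 6 the responses of the lines differed most, by list median, in squamous and ERK feedback genes. Relative to 2D, the mean of the squamous list was 1.84 to 1.85 in RWPE-1 and between -0.056 and 0.016 in LNCaP. Squamous genes differed downward in LNCaP in 18 of 33 cases and upward in 3 (19 and 3 adjusted over the list alone; median -1.28, camera adjusted p = 9.06e-06), with SERPINB3 at -5.05 ± 0.44 (-4.42 with the larger offset). Mitotic genes differed upward in 23 of 30 cases and downward in 1 (25 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 7.96e-10), with BUB1 at 1.34 ± 0.10, and hypoxia genes upward in 17 of 29 and downward in 4 (20 and 4 adjusted over the list alone; median 0.65, camera adjusted p = 4.8e-07). ADM differed by 2.28 ± 0.14. ERK feedback genes differed upward in 13 of 19 cases and downward in 1, also adjusted over the list alone (median 0.97, camera adjusted p = 4.8e-07). CCND1 differed by 1.49 ± 0.05. Metallothioneins differed downward in 6 of 9 cases, the same adjusted over the list alone (median -0.74, camera adjusted p = 0.000192). Desmosome genes differed downward in 11 of 19 cases and upward in 2 (11 and 3 adjusted over the list alone; median -0.80, camera adjusted p = 0.00303), a call that averaging probe sets ended (camera adjusted p = 0.153). Lysosome genes (16 of 25 downward, 1 upward; 16 and 2 adjusted over the list alone; camera adjusted p = 9.94e-06) and YAP/TAZ targets (9 of 23 upward, 3 downward; 11 and 5 adjusted over the list alone; camera adjusted p = 0.0331) were not called with an estimated correlation, at adjusted p = 0.0952 and adjusted p = 0.0612. The YAP/TAZ call was also lost without LNCaP day 6 replicate 1 (camera adjusted p = 0.0604). GJB6 differed by -7.39 ± 0.33 (-6.73 with the larger offset) and IGFBP3 by 5.50 ± 0.07. In all 4987 genes differed, 2522 upward and 2465 downward, 664 and 754 of them by 1 or more, against 2979 as deposited. The split was 3062 upward and 2160 downward after median centring and 2430 and 2707 after trimmed mean scaling.

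Across genes, which are not independent replicates, the gel responses of the lines correlated weakly, at a Pearson r of 0.04 at day 2 and 0.14 at day 6. Of 1635 genes called in both lines at day 2, 907 (55.5%) moved the same way, 532 upward where independent lists would share 260 and 375 downward where they would share 293. Calls in opposite directions also exceeded independence, with 441 genes higher in RWPE-1 and lower in LNCaP against 337, and 287 the other way against 225. At day 6 it was 1635 of 2477 (66.0%), 750 upward against 367 and 885 downward against 526, while calls in opposite directions numbered 472 against 453 and 370 against 427. As deposited the same-direction counts were 365 and 577. NDRG1 at day 6, and INSIG1 and ID1 at day 2, were among the genes that rose in both lines. Within RWPE-1, 1652 genes were called in the same direction at both days and 508 in opposite directions, where independent lists would share 360 upward and 363 downward. Within LNCaP, 2851 were called in the same direction and 70 in opposite directions, against 265 and 424. Unchanged groups simulated against the same 2D arrays shared at most 1 call in RWPE-1 and 0 in LNCaP. The covariance of the changes at the 2 days was 0.137 in RWPE-1 and 0.217 in LNCaP, against 0.0384 and 0.0381 in the simulations, which leaves 0.0990 and 0.178. The 3 arrays of a 2D group cannot be parted into 2 sets of at least 2 arrays, so part of the excess of shared calls over independent lists can come from the shared 2D arrays.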

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

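The results below were singled out because the lines differed in their response to the gel, and of the tests that weigh them, the admixture test and both tests of the hypoxia and mitosis lists were chosen after the results were seen.

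At day 2, 3989 genes responded differently. Under the rules for named genes, the most extreme upward in LNCaP relative to RWPE-1 were AKAP12 (8.72), IGFBP3 (8.45), ENO2 (5.80), PLOD2 (5.66) and ANGPTL4 (5.33). The most extreme downward were AKR1C2 (-5.31), AKR1C1 (-4.95), TMEFF2 (-3.40), MAF (-3.18) and OR51E1 (-2.998). Among gene lists, the largest upward median differences were those of hypoxia and glycolysis (1.502), NF-kB and inflammatory cytokines (1.27), immediate early genes (1.13), TGF-beta targets (1.06) and ERK feedback (1.00). Smaller upward medians were found for actin cytoskeleton (0.67), mesenchymal genes (0.48), interferon response (0.42), matrix proteases (0.42), tight junctions (0.36), YAP/TAZ targets (0.35), p53 targets (0.32), basement membrane (0.32), integrins (0.29) and luminal markers (0.22). Downward medians were found for mitosis (-1.09), DNA replication (-0.85), NRF2 antioxidant genes (-0.75) and lysosome (-0.35). The calls for mesenchymal genes, p53 targets, basement membrane, integrins and lysosome were lost with an estimated correlation (adjusted p = 0.0749, 0.0656, 0.0749, 0.162 and 0.209).

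At day 6, 4987 genes responded differently. Under the same rules, the most extreme upward in LNCaP relative to RWPE-1 were ANGPTL4 (6.82), AKAP12 (6.60), IGFBP3 (5.50), PLOD2 (5.50) and CYP26A1 (5.46). The most extreme downward were LY6D (-7.63), GJB6 (-7.39), FABP4 (-5.41), SPRR1A (-5.26) and AKR1C2 (-5.10). The list medians were 0.97 for ERK feedback, 0.65 for hypoxia and glycolysis, 0.57 for mitosis, 0.14 for YAP/TAZ targets, -0.57 for lysosome, -0.74 for metallothioneins, -0.80 for desmosomes and -1.28 for squamous differentiation. The calls for YAP/TAZ targets and lysosome were lost with an estimated correlation (adjusted p = 0.0612 and 0.0952). With no filter, where another probe set represents AKR1C2, its difference was 0.15 at day 2 and 0.11 at day 6, and that of AKR1C1 was -0.82 at day 2, none of them called. These values came from probe sets that had failed the filter on dim signals. The other probe set that passed the filter gave -5.06 and -5.02 for AKR1C2 and -5.49 for AKR1C1, but for both genes it can cross-hybridise, as can the one used. For TMEFF2 at day 2 another probe set differed by 1.55, in the opposite direction, and the mean of its probe sets by -1.48.

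Several genes that rose in LNCaP inside the gel, such as AKAP12, IGFBP3, EGR1 and MAFF, were far lower in LNCaP than in RWPE-1 in 2D. Genes called higher by 1 or more in the gel, with a called line difference in 2D between -9.42 (KRT19) and -3.02 (TRIB2), numbered 63 at day 2 and 54 at day 6. Carried-over RWPE-1 cells or RNA would raise all abundant RWPE-1 transcripts by the same share of their level in the RWPE-1 gel arrays of that day. The median share of 18 of them was 0.0623% at day 2 and 0.0295% at day 6, against 11.3% and 7.47% for the genes in question. The latter were chosen for their rise, and KRT15, ANXA1 and LAMB3 belonged to both sets at day 2. For AKAP12, IGFBP3, EGR1 and MAFF the shares at day 2 were 137%, 1564%, 157% and 153%. Their levels in LNCaP gels thus lay above those in RWPE-1 gels, which no admixture can reach. At day 6 the same held for IGFBP3 (159%), but not for AKAP12 (30.9%), EGR1 (33.5%) or MAFF (71.5%). At day 2, 6 of the 18 were themselves called higher, and at day 6, 5 were, with 1 called lower at each day, which a uniform admixture does not explain. Under each of 4 other scalings at least 96.3% of the genes were still called higher. These scalings moved the median of all genes in LNCaP by at most 0.10 at day 2 and 0.12 at day 6. The genes had been chosen for a rise of 1 or more, so keeping their calls was largely fixed in advance and does not weigh against scaling. A response of LNCaP cells may account for these rises, with line and medium not separable.

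The lines in 2D differed in the 3' to 5' ratio of ACTB and of the dap spike, so labelling that reached less far on the RWPE-1 arrays could have produced gene differences. Where a gene had 2 or more probe sets, they all lay on the same side in 88.2% of the genes higher in RWPE-1 (1140 of 1293) and in 81.3% of the genes higher in LNCaP (1147 of 1410). The share for the genes higher in RWPE-1 passed a bound of 80% that had been set beforehand as evidence against labelling. After the result was seen, that bound was judged wrong, since shorter labelling lowers signals and raises a gene in RWPE-1 only through the scaling, and since all probe sets of a gene can lie near its 3' end. Labelling and a difference between the lines therefore cannot be told apart by this test in either direction.

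The difference between the lines in the hypoxia and mitosis lists at day 2 was tested against scaling and against dependence on 1 array. Under 4 other scalings the median difference stayed between -1.05 and -0.942 for mitosis and between 1.38 and 1.48 for hypoxia and glycolysis, and a shift of all genes would move both the same way. Without any 1 of 12 arrays the medians stayed between -1.14 and -1.053 for mitosis (smallest size 1.053) and between 1.44 and 1.56 for hypoxia and glycolysis. The 4 scalings moved the median of all genes in that difference by 0.054 at most. This is small beside the list medians, so keeping them was largely fixed in advance. The opposite directions of the lists argue against a shift of all genes, and the second result argues against dependence on 1 array. Whether line or medium caused the difference stays open, since each line was grown in its own medium.

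The number of genes called was also compared with other ways of splitting the arrays. For the comparisons of 2 groups, 1 of 10 splits called as many genes as the real one, namely the real one itself, and the highest other counts were 5 (against 3382), 5 (6135) and 2 (5968) in RWPE-1, 8 (4700), 2 (4121) and 5 (2043) in LNCaP, and 0 (10069) between the lines. For these, 10 splits are too few for a share under 0.05. For the differences between responses, 1 of 100 drawn splits (of 200 possible) called as many, the highest other count being 2454 at day 2 and 3782 at day 6. The split that turns the labels of 1 whole line was not drawn, and it called 4737 and 6035 genes, because it adds the responses of both lines.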

How the results depend on the processing

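Of the alternatives, trimmed mean scaling and leaving out the arrays numbered 1 were chosen after the data had been seen. Of 130 list calls 104 were kept under every alternative apart from fry and the estimated correlation, and 94 were kept with the estimated correlation as well, while 578 of 686 calls of named genes were kept under every alternative. Using the values as deposited lowered the number of genes called to 1957 (from 3382) in RWPE-1 at day 2, 2328 (from 4700) and 1708 (from 4121) in LNCaP at days 2 and 6, 569 (from 2043) between its days, and 1897 (from 3989) and 2979 (from 4987) for the differences between responses at days 2 and 6. The overlaps fell with it, to 365 (from 907) and 577 (from 1635) across lines at days 2 and 6, 1046 (from 1652) within RWPE-1 and 1157 (from 2851) within LNCaP, and the cause was not tested. Leaving out 1 array gave 2695 to 3006 genes in RWPE-1 at day 2, 5547 to 5663 at day 6 and 5353 to 5475 between the days, and 4025 to 4333, 3495 to 3802 and 1649 to 1763 in LNCaP. The same gave 9737 to 9831 genes between the lines, and 3558 to 3842 and 4555 to 4870 for the differences between responses. Some results reversed, and beyond the choice of probe set given below the cause was not tested. With fry, which tests each list without reference to other genes, the direction of the test was opposite to that of camera, which had called none of them, for luminal markers (median 1.34) and Wnt targets (0.65) between the lines and androgen receptor targets (-0.43) in the day 2 difference between responses, while the medians were unchanged. With median centring the median of ribosomal proteins in that difference turned to 0.15. With no filter AKR1C2 reversed in RWPE-1 at day 2 (-0.28), in LNCaP at day 6 (0.26) and in the differences between responses (0.15 and 0.11), and CXCL2 between the lines (0.53). Each of these genes was then represented by a probe set that had failed the filter on dim signals. With the mean of all probe sets FASN (-0.0271) and KLK3 (-0.11) reversed in RWPE-1 at day 2, KLK3 (-0.33) at day 6, CCND1 (-0.17) between its days, PXN (0.023) between the LNCaP days, KLK3 (0.16) in the day 2 difference between responses, and HK2 (-0.18), KLK3 (0.59) and CDH1 (0.14) in that of day 6. The replicate block was checked by correlating the residuals of arrays with the same number: 0 of 9 pairs in either line exceeded 0.1, so the numbers were not used as pairs, although 8 of 9 pairs in LNCaP lay above 0 (highest 0.0876) and a weak pairing there is not excluded. With the block 3499, 6273 and 6103 genes were called in RWPE-1, 4801, 4254 and 2169 in LNCaP, 9331 between the lines, and 4087 and 5077 for the differences between responses, and it ended the calls of mesenchymal genes at day 2 (camera adjusted p = 0.0516) and YAP/TAZ targets at day 6 (0.0555) in the latter. It added calls of interferon genes in LNCaP at day 2 (0.034), oxidative phosphorylation between the lines (0.027) and ribosome biogenesis in the day 2 difference between responses (0.0468). Genes near the floor depend on the offset, so their fold changes are limited by signal over background.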

Other observations

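The tests of BMP, FOXO and aryl hydrocarbon receptor targets, and the second test of a shift toward RWPE-1, were chosen after the results that motivated them were seen.

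Several lists were called by camera in neither line for 3D against 2D. Notch targets gave camera adjusted p values of 0.451 and 0.2 in RWPE-1 at days 2 and 6 and 0.715 and 0.787 in LNCaP, and Wnt targets 0.544, 0.297, 0.573 and 0.942. Ribosomal proteins gave 0.858, 0.329, 0.503 and 0.858, but were called lower in RWPE-1 at day 2 after median centring (-0.13, adjusted p = 0.00257) and after trimmed mean scaling (-0.0884, adjusted p = 0.0183). Heat shock genes gave 0.291, 0.345, 0.361 and 0.33. The fibroblast and smooth muscle list gave 0.771, 0.54, 0.629 and 0.88, the immune list 0.552, 0.93, 0.573 and 0.88, and the endothelial list 0.552, 0.665, 0.585 and 0.858. The rotation test fry, which asks for a change of the list itself, called some of them, among these Wnt targets in RWPE-1 (adjusted p = 0.0433 and adjusted p = 0.000122) and in LNCaP (adjusted p = 2.38e-06 and adjusted p = 0.000888). For 3D against 2D, some further lists missed the camera threshold but passed it in several of the repeated analyses, namely metallothioneins (adjusted p = 0.06) and mesenchymal genes (adjusted p = 0.0637) and matrix proteases (adjusted p = 0.0722) in RWPE-1 at day 2, actin genes in RWPE-1 at day 6 (adjusted p = 0.2), actin genes in LNCaP at day 2 (adjusted p = 0.0599) and basal markers in LNCaP at day 6 (adjusted p = 0.0608). Of 15 neuroendocrine genes 4 were measured, too few for a test.

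TXNIP, which restrains glucose uptake, rose in RWPE-1 inside the gel by 1.34 at day 2 and 3.58 at day 6, and the stress protein SESN3 by 1.81 and 1.40. Both are known targets of FOXO factors, and 15 other targets were therefore tested as a list. At day 2, 6 rose and 0 fell (median 0.15, camera adjusted p = 0.00319, adjusted p = 0.0182 with an estimated correlation), including the cyclin CCNG2 (1.18 ± 0.06) and the adaptor KLHL24 (1.18 ± 0.13). At day 6, 8 rose and 1 fell (median 0.29, camera adjusted p = 0.0251, adjusted p = 0.0467 with an estimated correlation), with the apoptosis regulator BCL2L11 at 1.40 ± 0.11 and the kinase PDK4 at -1.05 ± 0.39. A FOXO response may thus be part of the change, which measurement of FOXO localization could test.

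ID1, ID2, ID3 and SMAD9 rose in RWPE-1 inside the gel, which raised the question of a BMP response. SMAD9 changed by 2.55 at day 2, but by only 0.11 on its other probe set that passed the filter. Of 14 other measured targets 3 rose and 2 fell at day 2 and 4 rose and 2 fell at day 6, with medians of -0.04 and -0.16 and a camera adjusted p of 0.445 at both days. The test pointed upward while the medians lay below 0, and the list as a whole does not speak for a BMP response. Those risen at day 6 were DLX2 (3.22), UNC5B (1.61), ID4 (1.39) and RUNX2 (0.74), and those fallen were TBX3 (-0.72) and MSX1 (-0.62). SMAD6, which was not in the list, rose by 4.24 at day 6 (1.04 and 1.22 on its other probe sets). ID1, ID2 and ID3 were left out of the list too, and they had been counted among the TGF-beta targets. The calls of the TGF-beta list therefore do not separate a TGF-beta response from a BMP response. A BMP response of single targets stays open. CYP1A1 rose in LNCaP, but 7 other targets of the aryl hydrocarbon receptor gave a camera adjusted p of 0.445 at day 2 (2 rose, 0 fell, median 0.0056) and 0.746 at day 6 (0 rose, 0 fell, median -0.13). Those risen at day 2 were CYP1A2 (2.78 ± 0.61) and TIPARP (0.37 ± 0.08). Most targets of the list did not follow CYP1A1, and a response of single targets stays open.

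Whether LNCaP moved toward the RWPE-1 profile in the gel was tested by correlating its day 2 change with the difference between the lines. The first test gave r = -0.119, but its bound was wrong: the reference difference used LNCaP day 6 arrays that carry the same gel response, which pulls r below 0, so it cannot tell. With the LNCaP 2D arrays split so that no array served both sides, r was 0.0505 to 0.0619, below the bound of 0.1, which argues against such a shift.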
